A study of Mus musculus with 6 samples.

How the data were processed

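The samples were 6 arrays of RNA from PbT-II CD4 T cells sorted from mouse spleen 7 days after infection with Plasmodium berghei ANKA, 3 from cells high for CD11a and CD49d and 3 from cells high for CD11a and low for CD49d. Per the labels' protocols, biotin-labelled cDNA was made from total RNA with a kit for small amounts. The deposited values are log2 expression values from RMA, per the submitters' processing notes, which state neither its version nor its variant; RMA corrects the background, normalizes quantiles across arrays and summarises probes into probe sets. They are given with 2 decimals, 1 column per array. Their range, up to 19.26, exceeds 16, the log2 limit of a 16-bit scanner, and differences are read on the deposited scale and not as folds. The labels call the samples biological replicates and do not say whether equal replicate numbers share a mouse, so p-values measure the spread between these samples. The labels name no batch. No pair of arrays held identical columns.

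Of 22206 probe sets, 19572 named 1 gene, none named several, and 2634 had no name in the annotation supplied. All 19572 matched a RefSeq table (mouse assembly GRCm38.p6) by gene ID, which was used for symbols, synonyms and the span of genes. The build behind the array annotation is not named, so no coordinates are given. Where a gene had more than 1 probe set (55 genes), the one with the highest mean over all arrays stood for it, which left 19505 genes. No filter on dim genes was applied.

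Each gene was compared between CD49d-hi and CD49d-lo with limma 3.58.1 (lmFit and eBayes without trend) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Itgal and Itga4 were also tested by exact two-sided permutation. The 37 gene lists comprised 25 of T cell programmes and cell functions, 9 of markers of other cell types (B and plasma cells, monocytes and macrophages, dendritic cells, neutrophils, erythroid cells, platelets, CD8 T cells, NK cells, gamma delta and innate-like T cells), and the sort integrins, housekeeping and background lists. The 32 programme and cell type lists with at least 5 measured genes were tested with camera (preset correlation 0.01), adjusted over these lists. Camera was repeated with a correlation estimated per list, and fry, which asks whether the genes of a list move on balance one way, gave 11 lists past the threshold. Camera gave 11 lists higher and 3 lower. A list's counts are given over all genes and adjusted over the list alone. The level that 90% of 49 background genes (transcripts restricted to other tissues) stay below was 6.17.

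The genes named are Itgal and Itga4; the 12 genes with the largest difference in each direction that passed the test, did not overlap between groups and lay above 6.17 in the higher group, leaving out predicted genes, antigen receptor segments and sex-linked marker genes; up to 3 called members per direction of each list, or the 2 with the smallest p where none was called; and 28 fixed genes of T cell differentiation. This rule, the lists, the tests and the alternatives were fixed before the data were examined. Itga2, Izumo1r, Nsg2, Top2a, Cenpe, Il18rap, Il1r2, C1qa, Csf1r, S100a6, Anxa4, Anxa6, Serpinb1a, Serpinb6b, Serpinb9b, Gbp3, Kif13a, Klrb1a, Klrb1f and Ncr1 fall outside the rule and were named after their values were seen. Fixed genes without a named probe set, Tcf7 and Foxp3 among them, are not analysed here.

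The per-gene test was tested on simulated data with 200 of 19505 genes changed in 20 runs: it recovered 9.1%, 85.8%, 97.0% and 99.0% of changes of 1, 2, 3 and 4 on the log2 scale, with 5.86% false calls and none of the wrong sign. In simulated lists of 30 genes, camera called a list shifted by 1 in 20 of 20 runs and 1 of 180 unshifted lists. The simulated genes were drawn independently of each other. These runs therefore cannot tell how often camera with the preset correlation calls unshifted lists in the real arrays, where genes of a list may vary together. The alternatives were a term for the replicate number, renewed quantile normalization, centring on the median or on the housekeeping list, a filter at the 75th percentile of the background list (5.63), the mean of a gene's probe sets, eBayes with trend and robust, array weights, leaving out each array, a minimum difference, other thresholds, and camera and fry as above. Added after seeing the data were a fit of 4 arrays, a fit of CD49d-hi replicate 2 alone against CD49d-lo, and removal of a trend over gene span from each array.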

Results

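PbT-II cells are CD4 T cells of a T cell receptor transgenic mouse line that recognise an antigen of malaria parasites. They had been transferred into mice, the mice had been infected with Plasmodium berghei ANKA, a malaria parasite of rodents, and the transferred cells were taken from the spleen 7 days later. The cells had been sorted by 2 surface integrins, CD11a (the integrin alpha L chain, encoded by Itgal) and CD49d (the integrin alpha 4 chain, encoded by Itga4). Both fractions were high for CD11a, a mark of T cells that have met antigen, and they differed in CD49d. RNA of each fraction was measured on 3 arrays, which gave 3 replicates with high CD49d (CD49d-hi) and 3 with low CD49d (CD49d-lo). The comparison asks which transcripts separate these fractions of antigen-experienced, malaria-specific CD4 T cells. All differences are CD49d-hi minus CD49d-lo on the deposited log2 scale, means are given with their SD, and n = 3 arrays per group throughout.

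The table held 22206 probe sets with values from 2.52 to 19.26, and the medians of the arrays lay between 5.92 and 6.06. Between 180 and 249 probe sets per array exceeded 16, the log2 limit of a 16-bit scanner, so no fold changes are given. Across genes, which are not independent replicates, Pearson's r was 0.967 to 0.984 between arrays of the same group and 0.942 to 0.969 between arrays of different groups. The first principal component held 46.9% of the variance, with all CD49d-hi arrays on one side and all CD49d-lo arrays on the other. The second held 24.0% and set CD49d-lo replicate 2 (score −69.20) and CD49d-hi replicate 3 (−20.87) apart from the other arrays, whose scores were positive. The number of arrays limits the precision of every value below. Of the named genes that passed, Gna15, Plek, Tmem163, Gzma, Ntrk3, Padi4, Havcr2, Serpinb9, Oas2, Hsd17b7, Cx3cr1, Fasl, Klra3, Nsg2, Il1r2, Anxa4 and Kif13a lay below the background level of 6.17 in their lower group, and Ephx1, Ly6c1, Ly6c2, Gzmb and Izumo1r above 16 in their higher group, so the size and rank of their differences are not given.

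Itga4 (probe set TC0200001158.mm.2) followed the sort. It stood at 13.43, 14.63 and 14.66 in the CD49d-hi arrays and at 9.85, 10.78 and 11.62 in the CD49d-lo arrays, a difference of 3.49 (SE 0.52, adjusted p = 0.0252 by limma). Itgal (TC0700001841.mm.2), for which both fractions had been gated high, stood at 16.30 ± 0.36 in CD49d-hi and 16.35 ± 0.40 in CD49d-lo, a difference of −0.05 (SE 0.29, adjusted p = 0.961); both means lie above 16, so this does not show equal amounts of transcript. Of these 2 genes 1 rose, also when adjusted over the list alone. An exact two-sided permutation test gave p = 0.10 for Itga4, the smallest that 3 arrays against 3 allow, and p = 0.50 for Itgal. The call for Itga4 was lost without CD49d-hi replicate 2 or 3 or without CD49d-lo replicate 1, where the difference was 3.30, 3.28 and 3.04 with adjusted p of 0.0936, 0.0820 and 0.0854.

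Most of the Th1 genes tested (19 of 26) were higher in CD49d-hi cells, and 5 of 30 follicular helper genes were lower. Of 19505 genes tested, 211 were higher in CD49d-hi and 70 were lower, and every one of these 281 genes differed by at least 1 on the log2 scale. Differences of 4 or more were seen in 43 of the higher genes and in 2 of the lower ones. Lgals3, which encodes the lectin galectin-3, had the largest difference of the named genes whose size is given, from 6.85 ± 0.08 in CD49d-lo to 14.37 ± 1.20 in CD49d-hi (difference 7.51, adjusted p = 0.00240). The others named were the cyclin-dependent kinase inhibitor Cdkn1a (6.54), the calcium-binding protein gene S100a4 (6.21), the G protein subunit gene Gna15, the chemokine genes Ccl4 (6.00) and Ccl3 (5.95), pleckstrin (Plek), Tmem163, Ccl5 (5.46), Gzma, Anxa2 (5.34) and Zbtb32 (5.34).

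Among the lower genes, Klrb1c, which encodes the receptor NK1.1, fell by 4.27, and Ntrk3 fell too. Bcl6, the transcription factor that directs follicular helper cells, fell by 3.83 to 6.30 ± 0.92 from 10.13 ± 1.24 in CD49d-lo (adjusted p = 0.0488). The others named were Tnfsf8 (−3.76), Padi4, Slc28a2b (−3.56), the epoxide hydrolase gene Ephx1, Atp1b1 (−3.28), Sccpdh (−3.26), Coro2b (−3.17), Igf1r (−3.07) and Nrip1 (−3.06). Klrb1c was also the lower gene with the smallest adjusted p of these (0.00135), with 14.19 ± 0.26 in CD49d-lo against 9.92 ± 0.32 in CD49d-hi. Of the 12 higher genes all but Gzma and Anxa2, and of the 12 lower genes Klrb1c, Tnfsf8, Ephx1 and Nrip1, passed in each fit that left out 1 array. Slc28a2b was lost without CD49d-lo replicate 1 alone (adjusted p = 0.0601), Anxa2 without CD49d-lo replicate 1 or 3 (adjusted p up to 0.0674), Padi4 without CD49d-hi replicate 2 or 3 or CD49d-lo replicate 3 (adjusted p up to 0.0766), and Ntrk3 and Coro2b without CD49d-hi replicate 2 or 3 or CD49d-lo replicate 1 or 3 (adjusted p up to 0.108 and 0.114), while Atp1b1 and Sccpdh were kept only without CD49d-hi replicate 3 (adjusted p up to 0.180 and 0.182 in the others).

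The groups did not overlap in 18.0% of all genes, against 10% by chance. Leaving out CD49d-hi replicate 1, 2 or 3 gave 135, 104 and 130 higher and 28, 15 and 23 lower genes, and leaving out CD49d-lo replicate 1, 2 or 3 gave 90, 261 and 88 higher and 16, 110 and 14 lower; 67 of the higher and 7 of the lower genes passed in each of these fits. Of the 69 genes named by rule that passed with all arrays, 29 passed in each of them as well, and 3 in none, Bcl6, Igf1r and Tnf (adjusted p of 0.0518 to 0.119, 0.0580 to 0.114 and 0.0731 to 0.165). Centring the arrays on a housekeeping list moved the median difference of all genes from −0.05 to −0.29 and the share of calls that were higher from 75.1% to 59.4%.

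**Figure D1:**
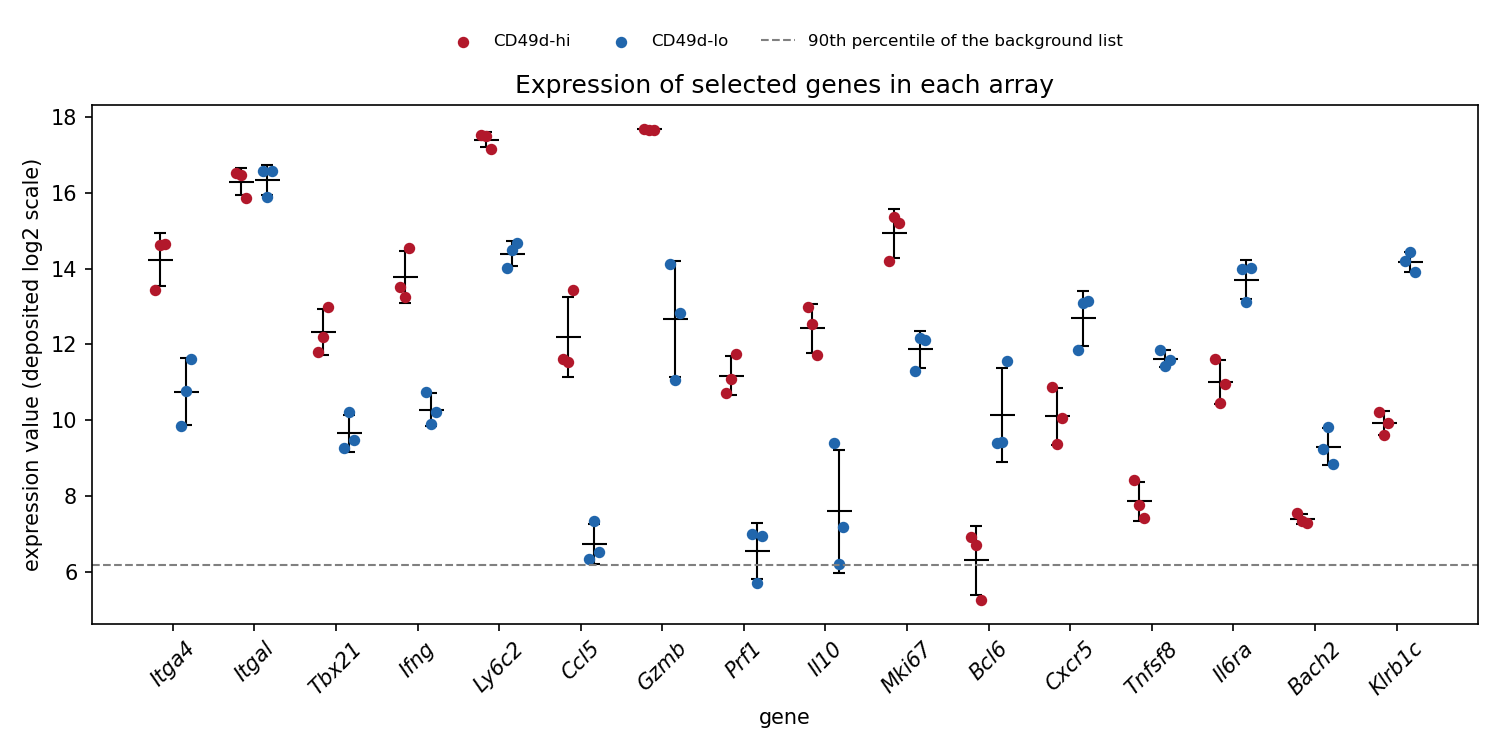
Deposited log2 values of 16 genes, named on the horizontal axis, in each CD49d-hi array (red) and CD49d-lo array (blue), with the group mean and SD as black bars and the 90th percentile of the background list (6.17) as a dashed line. Itga4 and the effector genes sit higher in all 3 CD49d-hi arrays, Bcl6, Cxcr5, Tnfsf8, Il6ra, Bach2 and Klrb1c sit lower, and Itgal overlaps.

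Th1 genes, those of the helper programme that makes interferon gamma, had the largest median difference of the tested lists (3.47). Of 26 measured members 19 rose and 1 fell, and 22 rose and 1 fell when adjusted over the list alone. Ifng rose by 3.49, to 13.77 ± 0.69 from 10.28 ± 0.43 (adjusted p = 0.00926), and Tbx21, which encodes the Th1 transcription factor T-bet, rose by 2.68 (adjusted p = 0.0227). The transcription factor genes Bhlhe40 (4.43) and Id2 (2.76), the receptor genes Havcr2, Il18r1 (3.92) and Cxcr6 (3.72), and Ly6c2 rose too. The cytokine gene Tnf went the other way and fell by 1.33 (adjusted p = 0.0488). The difference of Prdm1, which encodes Blimp-1, was 5.96 (SE 1.11) but missed the threshold (adjusted p = 0.0547, and 0.0195 without CD49d-lo replicate 2), and that of the chemokine receptor Cxcr3 was −0.09 (adjusted p = 0.905). Camera gave the list an adjusted p of 6.88e-27, and an adjusted p = 0.0467 with an estimated correlation, the only one of 32 tested lists past the threshold in both. Tbx21 missed the threshold without CD49d-hi replicate 2 or CD49d-lo replicate 1 or 3 (adjusted p up to 0.107), Ifng without CD49d-lo replicate 3 (adjusted p = 0.0549), Cxcr6 without any 1 CD49d-hi array or without CD49d-lo replicate 3 (adjusted p up to 0.0766), and Tnf in every such fit (adjusted p of 0.0731 to 0.165).

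Several genes of cytotoxic granules and killer receptors were higher. Camera gave the list an adjusted p of 8.28e-11, and an adjusted p = 0.0721 with an estimated correlation. Of 26 measured members 11 rose and 1, Klrb1c, fell, and 16 rose and 2 fell when adjusted over the list alone. Perforin (Prf1) rose by 4.63, to 11.18 ± 0.52 from 6.55 ± 0.74 (adjusted p = 0.00522). Granzyme B (Gzmb) rose to 17.68 ± 0.01 from 12.67 ± 1.54 (adjusted p = 0.0199), and the CD49d-lo arrays ranged from 11.07 to 14.13. Granzyme K (Gzmk) rose by 2.56, and granzyme A (Gzma) and Serpinb9, which encodes an inhibitor of granzyme B, rose from below background to 11.43 and 9.15. Gzmb missed the threshold without any 1 CD49d-hi array or without CD49d-lo replicate 3 (adjusted p up to 0.0875), and Gzma without CD49d-hi replicate 2 or any 1 CD49d-lo array (adjusted p up to 0.156). In the same arrays the mean of the monocyte and macrophage markers was 6.74, 5.93 and 7.11 in CD49d-hi and 5.54 to 5.69 in CD49d-lo.

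Among cytokines and chemokines, 8 of 31 measured genes rose and 2 fell, and 8 rose and 3 fell when adjusted over the list alone. Ccl3, Ccl4 and Ccl5, which encode chemokines that attract leukocytes, had the largest differences, and Il10, an anti-inflammatory cytokine gene, rose by 4.83 (adjusted p = 0.0329). Tnfsf8, the CD30 ligand gene, fell by 3.76. The median of the list was −0.0067 and its mean 0.89, and camera gave an adjusted p of 0.112 towards higher (0.0235 without CD49d-hi replicate 3), while fry gave 0.00366. Il10 missed the threshold without any 1 CD49d-hi array or without CD49d-lo replicate 3 (adjusted p up to 0.130), and Il4, a Th2 and follicular helper cytokine gene that rose by 2.61 (adjusted p = 0.0233), without CD49d-hi replicate 1 or 2 or CD49d-lo replicate 1 or 3 (adjusted p up to 0.109).

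The list of IL-10 and Tr1 genes, fixed in advance for regulatory IL-10 producers, had 5 of 19 members that rose and none that fell, and 7 and 1 when adjusted over the list alone. Membership in it does not show that a gene favours IL-10. The 5 were Bhlhe40, Havcr2, Cd226 (2.34), Il10 and Itga2 (2.52, adjusted p = 0.0480). Maf (−0.20, adjusted p = 0.910), Lag3 (−0.85, adjusted p = 0.566) and Eomes (0.15, adjusted p = 0.892), other members of the list, did not pass. Camera gave the list an adjusted p of 3.79e-04, and an adjusted p = 0.163 with an estimated correlation. The median of the list was 0.28 and its mean 1.26, with 12 positive and 7 negative differences. Bhlhe40, Havcr2 and Prdm1 (5.96, not past the threshold) are also in the Th1 list, so the list is not separate from the Th1 genes. Cd226 and Itga2 missed the threshold in 5 and 4 of the fits that leave out an array (adjusted p up to 0.103 and 0.175); only the fit without CD49d-lo replicate 2 kept Cd226, and only those without CD49d-hi replicate 1 or 3 kept Itga2.

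Some follicular helper genes were lower in CD49d-hi. Camera gave the list an adjusted p of 2.37e-07 towards lower, and an adjusted p = 0.0898 with an estimated correlation. Of 30 measured members of the Tfh list 5 fell and 1 rose, and 15 fell and 2 rose when adjusted over the list alone. Those that fell were Bcl6, Tnfsf8, the transcription factor gene Tox2 (−2.32), the IL-6 receptor gene Il6ra (−2.71) and Izumo1r, and the one that rose was Il4. Cxcr5, the receptor that draws T cells into B cell follicles, was 10.10 ± 0.76 against 12.69 ± 0.73, a difference of −2.59 that missed the threshold (adjusted p = 0.0557). The receptor genes Pdcd1 (0.49, adjusted p = 0.533) and Icos (adjusted p = 0.953), which follicular helper cells also carry, did not pass, and neither did Id3 (−1.14, SE 1.35, adjusted p = 0.797). Tnfsf8 passed in each fit that leaves out 1 array, Izumo1r in none (adjusted p of 0.0514 to 0.161), and Tox2 and Il6ra were lost without CD49d-hi replicate 2 or 3 or CD49d-lo replicate 1 or 3 (adjusted p up to 0.0727 and 0.107).

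Some genes of naive and central memory T cells were lower as well. Camera gave the list an adjusted p of 1.70e-04 towards lower, and an adjusted p = 0.0898 with an estimated correlation. Of 24 measured members 4 fell and none rose, and 8 fell and 1 rose when adjusted over the list alone. The 4 were Il6ra, the transcription factor gene Bach2 (−1.91, adjusted p = 0.0254), the chemokine receptor gene Cxcr4 (−2.62, adjusted p = 0.0399) and Nsg2 (adjusted p = 0.0467). The lymph node homing receptor gene Ccr7 was 11.79 ± 0.29 against 13.12 ± 0.24, a difference of −1.34 (adjusted p = 0.0530). The IL-7 receptor gene Il7r (1.34, adjusted p = 0.158), Klf2 (0.73, adjusted p = 0.652) and S1pr1 (0.42, adjusted p = 0.668), genes of resting and recirculating T cells, did not pass. Bach2 was kept only without CD49d-lo replicate 2 or 3, Cxcr4 only without CD49d-lo replicate 1 and Nsg2 only without CD49d-lo replicate 1, with adjusted p of up to 0.108, 0.148 and 0.159 in the other fits that leave out an array.

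Several genes of the cell cycle were higher in CD49d-hi. Camera gave adjusted p of 1.29e-22 for G1/S, with an adjusted p = 0.138 with an estimated correlation. For G2/M it gave 1.88e-24, with an adjusted p = 0.200 with an estimated correlation. Of 37 measured G1/S genes 7 rose, and of 41 G2/M genes 5 rose; none fell in either list, and 29 rose in each when adjusted over the list alone. The DNA replication genes Chaf1b (2.72), Mcm5 (2.56) and Mcm2 (2.05) rose, as did the mitotic genes Prc1 (3.62, adjusted p = 0.00135), Mki67 (3.06, adjusted p = 0.0164), Cdc20 (3.89), Top2a (2.72) and Cenpe (2.37). Mki67, which encodes the proliferation antigen Ki-67, stood at 14.93 ± 0.64 against 11.87 ± 0.49. The mean of the G2/M genes was 9.11, 9.88 and 10.82 in the CD49d-hi arrays and 7.38, 8.29 and 7.86 in the CD49d-lo arrays. Chaf1b and Prc1 passed in each fit that leaves out 1 array, and Mki67 only without CD49d-hi replicate 1 or CD49d-lo replicate 2 (adjusted p up to 0.0640 in the others); Mcm5, Mcm2, Cdc20, Top2a and Cenpe were lost in 3 or more of these fits, each without CD49d-hi replicate 2, CD49d-lo replicate 1 and CD49d-lo replicate 3, with adjusted p of up to 0.0943, 0.114, 0.108, 0.140 and 0.128.

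The type I interferon response list had 3 of 33 members that rose, none that fell, and 7 that rose when adjusted over the list alone. They were the RNA sensor gene Ddx58 (1.77), Ifi35 (1.35) and the oligoadenylate synthetase gene Oas2. Camera gave an adjusted p of 3.17e-07, and an adjusted p = 0.282 with an estimated correlation. The mean of the list was 10.94, 10.79 and 10.07 in the CD49d-hi arrays and 9.71, 10.05 and 9.94 in the CD49d-lo arrays, so CD49d-hi replicate 3 stood near CD49d-lo replicate 2. In the same arrays the mean of the monocyte and macrophage markers was higher in CD49d-hi by 0.96. Within CD49d-hi that marker mean was 6.74, 5.93 and 7.11. It was highest in CD49d-hi replicate 3, where the interferon mean was the lowest of these arrays, so the lists did not rise together there. Each of the 3 genes passed in only 1 of the fits that leave out an array, Ddx58 and Ifi35 without CD49d-lo replicate 2 and Oas2 without CD49d-hi replicate 3, and adjusted p in the other fits reached 0.0936, 0.114 and 0.132.

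Few metabolic genes passed. None of 52 oxidative phosphorylation genes passed, over all genes or adjusted over the list alone, while 49 of them had positive differences with a median of 0.47; Ndufa9 (1.03, adjusted p = 0.109) and Sdhb (0.93, adjusted p = 0.116) had the smallest p. Their mean was 13.42, 13.37 and 14.03 in the CD49d-hi arrays and 12.74, 13.71 and 12.81 in the CD49d-lo arrays, so the groups overlapped. The mean difference of 0.52 became 0.31 without CD49d-hi replicate 3 and 0.83 without CD49d-lo replicate 2. Camera gave an adjusted p of 3.17e-07, and an adjusted p = 0.522 with an estimated correlation. Of 19 cholesterol synthesis genes 1 rose, Hsd17b7 (adjusted p = 0.0255), also when adjusted over the list alone, and camera gave an adjusted p of 1.70e-04, and an adjusted p = 0.282 with an estimated correlation. Hsd17b7 was kept only without CD49d-hi replicate 1 (adjusted p up to 0.114 without another array). None of 19 genes of amino acid transport and the serine pathway passed by either adjustment, with Slc3a2 at 1.02 and Shmt2 at 1.31, and camera gave an adjusted p of 0.0251, and an adjusted p = 0.200 with an estimated correlation. That call was lost without CD49d-hi replicate 1, CD49d-lo replicate 2 or CD49d-lo replicate 3 (adjusted p up to 0.170).

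All 40 measured ribosomal protein genes had negative differences, and none passed by either adjustment (Rpl6, adjusted p = 0.238; Rpl19, adjusted p = 0.287). The size is not given, since the mean of the list lay above 16 in every array. The groups overlapped in that mean, with CD49d-hi replicate 3 (16.88) above CD49d-lo replicate 1 (16.84) and CD49d-lo replicate 3 (16.61). Camera gave an adjusted p of 2.85e-05 towards lower, and an adjusted p = 0.578 with an estimated correlation. The call was lost without CD49d-lo replicate 2 (adjusted p = 0.0878). None of 21 glycolysis genes passed over all genes and 1 did when adjusted over the list alone, the glucose transporter gene Slc2a3 (2.42, adjusted p = 0.0503 over all genes and 0.0302 without CD49d-hi replicate 1), while Ldha differed by 0.87 (adjusted p = 0.304); camera gave an adjusted p of 0.564. Fatty acid oxidation had no call among 19 genes by either adjustment (Acadl 1.34, Acads 0.91), with a median of 0.12, a mean of −0.05 and an adjusted p of 0.782 towards lower.

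**Figure D2:**
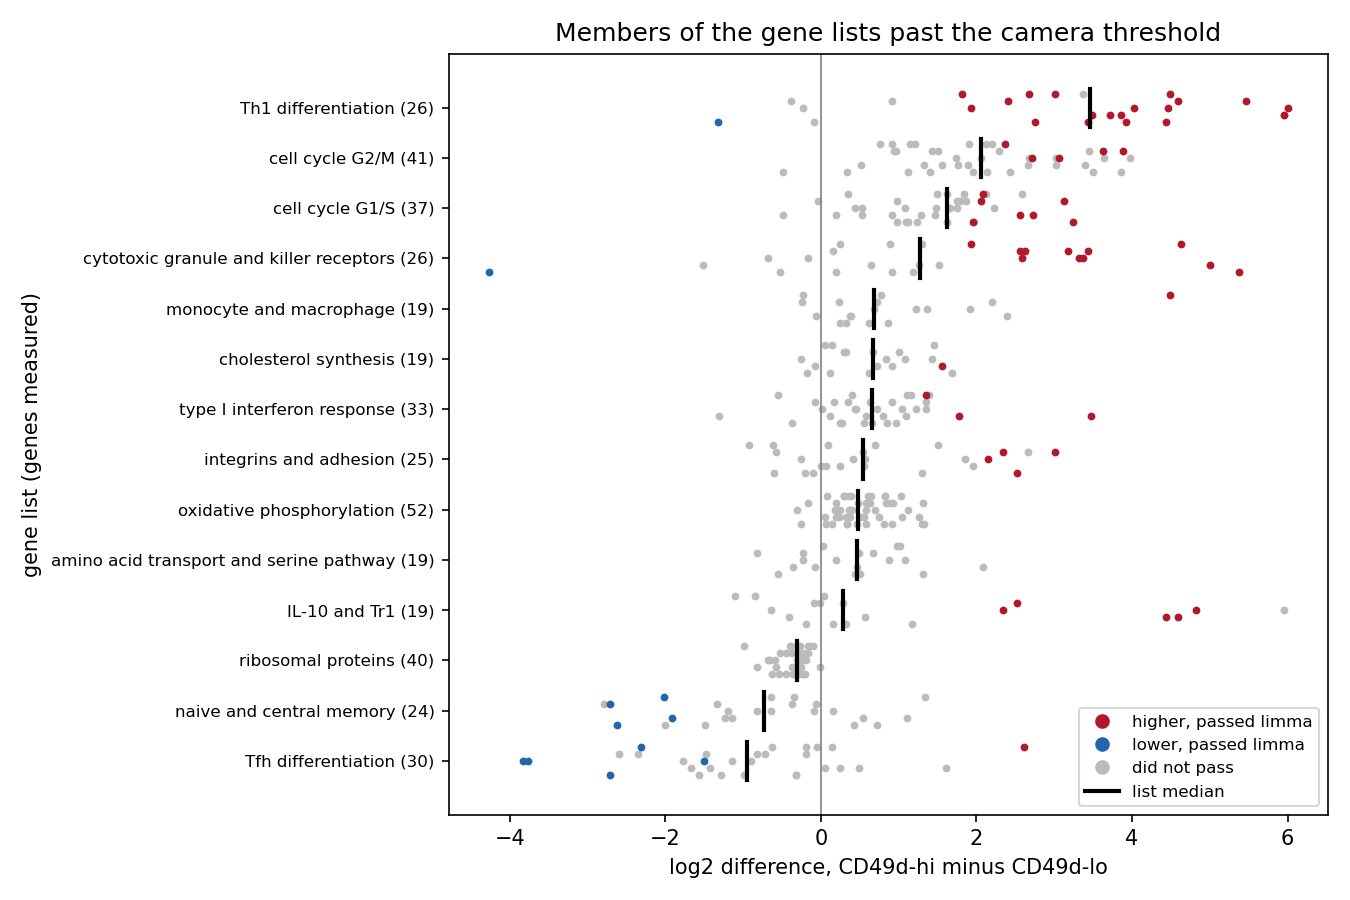
Log2 differences (CD49d-hi minus CD49d-lo, horizontal axis) of every measured gene in the 14 lists past the camera threshold (vertical axis, genes measured in brackets), with genes that passed limma in red (higher) or blue (lower), the others in grey and the list median as a black line. Medians run from 3.47 for Th1 differentiation to −0.95 for Tfh differentiation, and the oxidative phosphorylation and ribosomal protein lists hold grey points alone.

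Integrin and adhesion genes had 4 of 25 members that rose, none that fell, and 8 that rose with 1 that fell when adjusted over the list alone. Ly6c2 and Ly6c1, which encode the Ly6C surface protein of effector T cells, Cd226 and Itga2 rose. The partner chains of CD49d did not pass: Itgb1 differed by 1.85 (12.68 ± 0.72 against 10.84 ± 0.64, adjusted p = 0.116) and Itgb7 by 0.24 (adjusted p = 0.683). Camera gave the list an adjusted p of 1.70e-04, and an adjusted p = 0.0898 with an estimated correlation. Ly6c1 missed the threshold without CD49d-hi replicate 2 or CD49d-lo replicate 1 or 3 (adjusted p up to 0.0575).

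Receptors went both ways. Of 25 cytokine receptor genes 4 rose, Il18r1, Il18rap (3.86), Ifngr1 (4.02) and Il12rb1 (2.41), and 4 fell, Il6ra, Tgfbr3 (−2.14), Ifnar2 (−1.47) and the decoy receptor gene Il1r2; 7 rose and 5 fell when adjusted over the list alone. The median was −0.08 and the mean 0.33, and camera gave an adjusted p of 0.594 towards higher. Of 20 chemokine receptor and egress genes 3 rose, Cx3cr1, Ccr2 (4.49) and Cxcr6, and 1 fell, Cxcr4; 4 rose and 3 fell when adjusted over the list alone, and camera gave an adjusted p of 0.132 and fry 0.0282. Il18r1 and Cx3cr1 passed in each fit that leaves out 1 array; Ifngr1, Il12rb1 and Il18rap were lost without CD49d-hi replicate 1 or 2 or CD49d-lo replicate 1, and Ccr2 without CD49d-hi replicate 1 or 2 or CD49d-lo replicate 3 (adjusted p up to 0.0793, 0.0949, 0.114 and 0.0715). Tgfbr3 was kept only without CD49d-lo replicate 2, Ifnar2 only without CD49d-hi replicate 3 and Il1r2 only without CD49d-lo replicate 2 (adjusted p up to 0.128, 0.129 and 0.125).

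Of 23 inhibitory receptor and exhaustion genes 4 rose and 1 fell, and 5 rose and 5 fell when adjusted over the list alone. Havcr2 (TIM-3), the ectonucleotidase gene Entpd1 (4.24, adjusted p = 0.00564), Lilrb4a (4.10) and Ctla4 (2.86) rose and Tox2 fell; camera gave an adjusted p of 0.318. Ctla4 was also the only one of 14 Treg genes that rose (5 when adjusted over the list alone, none fell by either adjustment; camera adjusted p = 0.0922). Il4 was the only one of 15 Th2 and Th17 genes that rose (2 when adjusted over the list alone, none fell; median −0.19, mean 0.09, camera adjusted p = 0.705 towards lower). Lilrb4a was lost without CD49d-hi replicate 1 or 2 or CD49d-lo replicate 3 (adjusted p up to 0.0921), and Ctla4 was kept only without CD49d-hi replicate 3 (adjusted p up to 0.157 in the others). The Treg list passed without CD49d-hi replicate 3 (adjusted p = 0.0211) and without CD49d-lo replicate 1 (adjusted p = 0.0360).

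Genes of the T cell receptor complex and its kinases did not pass in any of 20 cases by either adjustment (Cd6 1.10, adjusted p = 0.105; Thy1 1.91, adjusted p = 0.153; camera adjusted p = 0.718). Of 27 genes of T cell receptor signalling and early activation 1 rose, the phosphatase gene Dusp5 (3.99, adjusted p = 0.00288), with 2 that rose and 1 that fell when adjusted over the list alone and a camera adjusted p of 0.163 (0.0336 without CD49d-hi replicate 3). Of 23 apoptosis regulators 2 rose, the survival gene Bcl2l1 (3.26, adjusted p = 0.00789) and the death ligand gene Fasl (adjusted p = 0.0304), with 5 that rose and 1 that fell when adjusted over the list alone and a camera adjusted p of 0.157 (fry 0.0192). Fasl was lost without CD49d-hi replicate 2 or 3 or CD49d-lo replicate 1 or 3 (adjusted p up to 0.109). None of 20 stress and dissociation genes passed by either adjustment (Gadd45b 1.25, Junb 0.76; camera adjusted p = 0.718), and none of 13 housekeeping genes (Ppia, adjusted p = 0.267; Tbp −0.78) or of 49 tissue-restricted genes used as background (Tg 1.31, Tnp2 −0.86) did.

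Few markers of other cell types passed. Of 19 monocyte and macrophage genes 1 rose, Ccr2, which T cells also express, with the same count when adjusted over the list alone, and the list was higher by a mean of 0.96 (camera adjusted p = 1.62e-04, and adjusted p = 0.282 with an estimated correlation). Differences were positive for 16 of the 19 genes, and without Ccr2 the 18 other genes were still higher by a mean of 0.76. C1qa, a complement gene of macrophages, was 8.06, 5.64 and 9.57 in the CD49d-hi arrays and 5.01 to 5.82 in the CD49d-lo arrays, a difference of 2.39 (SE 0.88) that missed the threshold. Of 15 B and plasma cell genes none passed over all genes and 1 rose when adjusted over the list alone, Jchain, the immunoglobulin joining chain gene, with 11.60, 7.14 and 8.97 in CD49d-hi and 4.11 to 4.99 in CD49d-lo (adjusted p = 0.0774 over all genes); Cd79b differed by 1.73 (adjusted p = 0.197), and camera gave the list an adjusted p of 0.112 (0.0170 without CD49d-hi replicate 2). Of 8 NK cell genes Klra3 and Gzma rose and Klrb1c fell, by either adjustment, with a camera adjusted p of 0.163.

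No dendritic cell (14 genes), neutrophil (12), erythroid (9) or platelet (7) marker passed over all genes, with camera adjusted p of 0.378, 0.644, 0.558 and 0.980, and 1 dendritic cell marker rose when adjusted over its list alone, the class II gene H2-Eb1 (2.10, adjusted p = 0.0795 over all genes and 0.0467 without CD49d-hi replicate 2). Cst3 differed by 1.02, Mmp8 by −0.73, S100a9 by 0.38, Klf1 by −0.39, Slc4a1 by −0.46, Treml1 by −0.27 and Ppbp by 0.27. For platelet genes the median of −0.06 and the mean of −0.010 lay below 0 while camera pointed higher. Cd8b1 was 11.69 ± 0.93 in CD49d-hi and 11.01 ± 1.37 in CD49d-lo, and Cd8a, at 5.79 ± 0.20 in CD49d-lo, near background, differed by 0.12; neither passed (adjusted p = 0.774 and 0.879). Of 4 genes of gamma delta and innate-like T cells none passed by either adjustment (Sox13 0.10, Cd163l1 −0.12).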

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

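The fit of 4 arrays, the fit of CD49d-hi replicate 2 alone and the removal of the gene span trend were chosen after the data were seen. Signal over background limits dim genes: 10838 of 19505 genes lay above the 75th percentile of the background list, and testing these alone gave 286 higher and 92 lower genes. No call changed direction under any alternative that was run, and the genes and lists named below for a change of sign or direction passed in neither fit. Removing probe sets by the ending of their IDs was not run, because the array has no such IDs. Against 211 genes higher and 70 lower, renewed quantile normalization gave 205 and 103, centring on the median 218 and 57, the mean of probe sets 211 and 70, a minimum difference of 1 the same 211 and 70, eBayes with trend and robust 224 and 74, and removal of the span trend 232 and 71. Centring on the housekeeping list gave 277 higher and 189 lower, with 188 and 69 shared, array weights 340 and 140, with all 211 and 70 shared, a threshold of 0.01 68 and 7, and a threshold of 0.10 428 and 170; apart from the thresholds, the cause was not tested. Leaving out 1 array gave 88 to 261 higher and 14 to 110 lower, and the cause was not tested. Without CD49d-hi replicate 3 and CD49d-lo replicate 2, the 4 other arrays gave 289 and 123, of which 161 and 45 were shared, again with the cause not tested. CD49d-hi replicate 2 alone, assumed to vary like the CD49d-lo arrays, gave 3 and 0 by limma, with 1463 genes at an unadjusted p under 0.05.

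For arrays of equal replicate number, the deviations from the group means correlated across genes at 0.20, −0.29 and −0.27. CD49d-hi replicate 3 went best with CD49d-lo replicate 2 (0.44) and CD49d-hi replicate 2 with CD49d-lo replicate 3 (0.22). Deviations of 3 arrays from their own mean depend on each other, so these values cannot tell whether equal numbers share a mouse. With a replicate block the counts were 88 higher and 10 lower, of which 86 and 9 were shared; the cause was not tested. The block brought the Treg list just past the threshold, turned the direction of the platelet list (mean −0.010) and changed no other list's call. Counted over all alternatives, the values of named genes kept their direction and side of the threshold 2163 times, lost the threshold 418 times, gained it 40 times and changed sign 26 times. The 2163 include genes that passed in neither fit, and the other thresholds, which cannot change a direction. They also include the mean of a gene's probe sets, where all 138 genes counted stayed the same. The 2163 therefore do not measure how stable the calls are. Of the 69 genes named by rule that passed with all arrays, 29 passed in every fit that left out an array.

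Camera with an estimated correlation gave 1 list higher and 0 lower instead of 11 and 3, with 7 at an unadjusted p under 0.05. Only the correlation setting differed between these camera runs, so the loss of lists comes from that setting. This does not show that correlation among the genes of a list caused the loss. What else the setting changes in the test was not separated from it. Fry gave 9 and 2, and why it differs from camera was not tested. Fry lost the interferon, oxidative phosphorylation, cholesterol, amino acid, ribosomal and monocyte lists and newly passed cytokines and chemokines, chemokine receptors and apoptosis regulators. Under the other alternatives 9 to 15 lists were higher and 2 or 3 lower. The amino acid list was lost after renewed quantile normalization (adjusted p = 0.165), under the background filter and with CD49d-hi replicate 2 alone, which also lost the monocyte list. Itga4 stayed higher throughout, at 3.04 to 3.93 when 1 array was left out, and missed the threshold without CD49d-hi replicate 2 or 3 or CD49d-lo replicate 1, with 4 arrays (3.30), with CD49d-hi replicate 2 alone (3.88) and at a threshold of 0.01 (3.49); its adjusted p ranged from 0.00499 to 0.227. Itgal ranged from −0.28 to 0.16 with 1 array left out and was 0.13 with CD49d-hi replicate 2 alone.

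The cause of the other changes was not tested. For genes the sign of the difference changed. For lists camera's direction against the other genes turned, and the value given is the mean difference, which need not change sign. The mean changed sign under some alternative only for the T cell receptor complex, neutrophil, fatty acid oxidation, platelet, Th2 and Th17, glycolysis and erythroid (−0.16 to 0.029 with 1 array left out) lists, none of which passed under any alternative. Renewed quantile normalization gave Icos −0.14 and mean differences of −0.13 for the T cell receptor complex and 0.20 for cytokine receptors. Centring on the housekeeping list gave Cd8a −0.13, Sox13 −0.15, Icos −0.20, Eomes −0.095, Itgb7 −0.0021, Ncr1 −0.032 and the platelet list −0.26. The background filter gave the Th2 and Th17 list 0.49 and the T cell receptor complex 0.0033. Array weights and fry turned the platelet list (−0.010). The 4 arrays gave Cxcr3 0.035, Eomes −0.075, fatty acid oxidation 0.073 and the platelet list −0.13. CD49d-hi replicate 2 alone gave Ppbp −0.07, Cd8a −0.037, Cd163l1 0.12, Cxcr3 0.027, Icos −0.11, glycolysis 0.019, fatty acid oxidation 0.084 and the platelet list −0.059. With 1 array left out the values ran from −0.12 to 0.14 for Icos, −0.67 to 0.14 for Maf, −0.017 to 0.45 for Ncr1, −0.34 to 0.18 for Cd163l1, −0.04 to 0.46 for Eomes, −0.0017 to 0.27 for Sox13, −2.24 to 0.40 for Id3, −0.27 to 0.15 for fatty acid oxidation, −0.30 to −0.0091 for stress genes and −0.10 to 0.092 for the platelet list.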

Other observations

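The families in the first paragraph, the test for NK cells, the test of the span trend as the whole cause, the removal of that trend and the fit of CD49d-hi replicate 2 alone were chosen only after the results were seen. The higher genes included some of the calcium-binding S100a genes and the membrane-binding annexins. Of 13 S100a genes 2 rose, S100a4 by 6.21 and S100a6 by 3.58, and of 12 annexin genes 3 rose, Anxa2 by 5.34, Anxa6 by 4.51 and Anxa4 to 7.69 from below background, while none fell in either family. Of 26 serpinb genes, which encode intracellular protease inhibitors, 4 rose, Serpinb9 from below background to 9.15, Serpinb6b by 3.36, Serpinb9b by 3.28 and Serpinb1a by 2.97, and none fell. The guanylate-binding protein gene Gbp3 rose by 2.44, 1 of 6 genes of its family. The families were chosen for their called members, so no test of a family as a whole is given. Of 34 kinesin genes 1 fell, Kif13a, and of 9 genes of TNF superfamily ligands 1 fell, Tnfsf8. S100a4, S100a6, Anxa6, Serpinb9, Gbp3 and Tnfsf8 passed in each fit that leaves out 1 array, while Anxa4 was kept only without CD49d-hi replicate 2 (adjusted p up to 0.134 in the others), Serpinb6b was lost without CD49d-lo replicate 3 (0.0505), Serpinb9b without CD49d-hi replicate 2 or CD49d-lo replicate 1 or 3 (up to 0.107), Serpinb1a without CD49d-hi replicate 1 or 2 or CD49d-lo replicate 1 or 3 (up to 0.0958), and Kif13a without CD49d-hi replicate 2 or 3 or CD49d-lo replicate 1 or 3 (up to 0.128). Among the 2634 probe sets without a gene name, 16 were higher and 9 lower in CD49d-hi when all probe sets were tested together.

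Macrophage and plasma cell transcripts were raised in CD49d-hi replicates 1 and 3, where Jchain stood at 11.60 and 8.97 and C1qa at 8.06 and 9.57, against 7.14 and 5.64 in CD49d-hi replicate 2, which for Jchain is still above CD49d-lo (4.11 to 4.99). Sorting on the transferred cells' marker should remove such cells, and of the 19 macrophage markers 1 is also in a T cell list. RNA from them could raise other genes in the same arrays, so the 104 genes called higher without CD49d-hi replicate 2 were looked up in it. Their median excess over CD49d-lo was 2.98 there and 3.34 in the other CD49d-hi arrays. This share of 89.4% (bootstrap interval over genes 79.3% to 97.1%), against 45.6% for Jchain itself, argues against such RNA as the source of these calls as a set. A median cannot exclude it for a minority of the genes, and Jchain and the macrophage marker Csf1r are among the 104. Csf1r stood at 6.79 and 6.56 in CD49d-hi replicates 1 and 3. In CD49d-hi replicate 2 it stood at 4.29, near its CD49d-lo mean of 3.96. The interval does not cover the spread between arrays, and CD49d-hi replicate 2 is 1 array. The same CD49d-lo arrays had served to call these genes, which can raise the share, and by how much was not tested. Such RNA stays open for the markers themselves, whose mean with CD49d-hi replicate 2 alone was 0.30 above CD49d-lo instead of 0.96, and no biological explanation was tested. That mean includes Ccr2, which T cells also express and which stood at 12.52 in CD49d-hi replicate 2 against a mean of 7.83 in CD49d-lo. The 0.30 is therefore not a measure of macrophage RNA alone in CD49d-hi replicate 2.

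CD49d-hi replicate 3 and CD49d-lo replicate 2 deviated from their groups in the same genes (r = 0.44 across genes). A candidate explanation is a yield of RNA or label that depends on the span of a gene: over 9307 genes above background, their shared deviation correlated with log2 span at Spearman's rho of −0.33, with a median of 0.22 in the 2327 shortest genes and −0.18 in the 2327 longest. Removing that trend from each array left the correlation of the deviations at 0.43, against 0.44 before. The span trend therefore accounted for little of that correlation, which argues against span as the whole cause. The difference between CD49d-hi and CD49d-lo also followed span over these 9307 genes (Spearman's rho −0.17). Its median was 0.15 in the 2327 shortest genes and −0.14 in the 2327 longest. Removing the trend from each array kept 210 of 211 higher and 66 of 70 lower genes. What else the arrays share stays open, since the labels name no batch, and no biological explanation was tested.

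Klrb1c fell by 4.27 while granzyme and perforin genes rose. NK cells in the CD49d-lo fraction, which sorting on the transferred cells' marker should remove, could carry it, but the 7 other NK cell markers, 3 of all 8 also in a T cell list, had a median of 4.98 there, below the background level of 6.17, and Ncr1, an NK cell receptor gene, stood at 4.47, which argues against them, although Eomes, which T cells also express, stood at 7.30. Signal from another Klrb1 gene on these probes needs one that is abundant in CD49d-lo and lower in CD49d-hi: of 4 others measured the most negative difference was −0.93 (Klrb1a, at 5.04 in CD49d-lo), and the only one above background, Klrb1f, differed by 3.11 in the other direction (adjusted p = 0.132). The bound set in advance asked that such a gene differ by less than 1 either way, which was wrong for a gene that is higher in CD49d-hi, as it cannot supply the signal. Lower Klrb1c transcript in CD49d-hi T cells stays a hypothesis from the same data.

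The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For the genes higher and for the genes lower in CD49d-hi, 1 of the 10 splits, the real one, gave as many (211 and 70), and the highest of the others was 0 for both by limma, with up to 1865 genes at an unadjusted p under 0.05. For lists, either direction of a split was counted. For lists higher, 1 of 10 gave as many as the real 11, and the highest other gave 6. For lists lower, 8 of 10 gave as many as the real 3, and the highest other gave 6.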
